A study of Arabidopsis thaliana with 12 samples.

How the data were processed

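The values are 12 Affymetrix expression arrays hybridised with RNA of 5-day-old Arabidopsis thaliana seedlings of the Col-0 ecotype. The arrays fall into 4 groups of 3: wild type untreated, wild type irradiated, gmi1-1 untreated and gmi1-1 irradiated. Groups and replicate numbers were taken from the sample titles, which call the replicates biological. Per the labels' protocols, seeds were kept at 4 °C for 2 days on half-strength medium and grown at 21 °C in continuous light, and the irradiated plates received 100 Gy of gamma rays from a cobalt source at 27 to 34 Gy per minute and were harvested 1.5 h later. The labels do not say whether the untreated plates were carried to the source and back. RNA was isolated with Tri-Reagent, treated with DNase and labelled with biotin in a one-cycle reaction, per the labels' protocols.

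The deposited values are log2 expression values, 1 per probe set and array, which the authors summarised and normalized with GCRMA, per the submitters' processing notes. GCRMA corrects the background by a model of probe sequence, normalizes between arrays and summarises the probes of a set on the log2 scale, and it compresses values near background. Its version, the array design and the probe set definitions are not given in the sources used here. The log2 scale was taken from the range of the values. The quartiles of the arrays differ, so the deposited values were not forced to 1 common distribution over the loci in the table. Each probe set is named by an Arabidopsis locus. The table holds 16947 loci and 2 control probe sets, and loci outside it were not analysed here. Of the loci, 16851 matched the RefSeq annotation of assembly TAIR10.1 by locus tag, which gave a gene name for 7512. That annotation served for names, gene length and the order of neighbouring genes. Since no genome build is named with the array, no coordinates are given. Where the annotation has neither a symbol nor a short synonym, the locus is printed. The position of the GMI1 probes relative to the T-DNA insertion is not given in the sources used here.

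Loci were kept where at least 3 of the 12 arrays had a log2 value of 4 or more, which left 9889 loci for testing. A linear model with a mean for each of the 4 groups was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that the groups shared 1 estimate of the spread per locus. The contrasts were irradiation in wild type, irradiation in gmi1-1, irradiation over both genotypes, the difference in the irradiation effect between genotypes (gmi1-1 minus wild type), and gmi1-1 against wild type untreated, irradiated and over both treatments. P-values are limma's two-sided moderated p-values with Benjamini-Hochberg adjustment over the 9889 loci of a contrast, and a locus is said to have risen or fallen where its adjusted p lay under 0.05. Standard errors are those of limma's moderated fit. The number of arrays limits the precision.

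The size of the gmi1-1 response relative to wild type was summarised as a total least squares slope through the origin over the loci called for irradiation over both genotypes. Gene lists were tested with limma's camera, two-sided, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a contrast, and again with an estimated correlation. The self-contained test of limma's fry stands beside it, which asks whether the genes of a list move, on balance, in 1 direction. Camera compares the moderated statistics of a list with those of all other loci. Calls within a list are counted over all loci tested and also adjusted over the list alone. There were 22 lists with 307 loci, of which 221 were measured: DNA damage response markers, homologous recombination, end joining, excision and photo repair, damage checkpoint kinases and sensors, cohesin and SMC, G2 and M phase, S phase and replication, CDK inhibitors, oxidative stress, heat shock, touch and early stress, jasmonate, salicylate and defence, ethylene, abscisic acid and drought, auxin, circadian clock, photosynthesis, root markers, seed storage, and shoot meristem and stomatal lineage. Several loci stand in more than 1 list.

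The contrasts, the filter, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named, for irradiation in each genotype, the 15 largest rises and 10 largest falls among called loci with a gene name whose irradiated arrays all lay on 1 side of the untreated arrays. For the other contrasts it took up to 10 genes in each direction, or the 3 smallest p-values where fewer than 3 passed, and for each list 2 to 4 members with the smallest p. GMI1 is named throughout. Of the genes the rule picks, 2 are not reported here.

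The alternatives fixed in advance were the replicate number as a block, no filter, a filter at a log2 value of 6, quantile normalization, median centring, an intensity trend or a robust prior in eBayes, array weights, a fit of only the groups compared, a size threshold of log2 1, and leaving out each array in turn with the 9889 loci held fixed. After the data were seen, 2 fits were added: without the gmi1-1 libraries labelled untreated replicate 1 and irradiated replicate 1, which leaves 2 arrays in each gmi1-1 group, and without these and gmi1-1 irradiated replicate 3, which leaves 1 array labelled gmi1-1 irradiated and assumes that it varies like the other groups. The gmi1-1 response is described in the former, with its genes picked by the same rule, beside the values of all 12 arrays.

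The procedure was tested on simulated data: in each of 10 simulations of 9889 loci, 200 loci were changed in the arrays standing for irradiated wild type, over noise with the residual spreads of the real loci in shuffled order. For irradiation in wild type, 35.5% of the changes of log2 1, 82.5% of those of 2 and 94.7% of those of 3 were recovered, and 5.88% of the calls were false. For the difference between genotypes, 8.51%, 56.9% and 83.0% were recovered, and 5.00% of the calls were false. Camera called a list of 20 loci raised by 0.7 in 10 of 10 simulations and a list left alone in 0 of 10. The noise was drawn independently for each locus, so the simulated lists held no correlation between genes. In the data the damage response markers other than GMI1 had an estimated correlation of 0.936 with all 12 arrays. It was 0.728 without the library labelled gmi1-1 untreated replicate 1. Without this library and the one labelled gmi1-1 irradiated replicate 1 it was 0.276, so its size depends on these 2 libraries. The check therefore does not cover lists of correlated genes, nor recovery where a large spread goes with a large change.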

Results

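Transcript levels were measured on 12 arrays of whole Arabidopsis seedlings, 3 biological replicates per the labels in each of 4 groups: wild type and gmi1-1, untreated or harvested 1.5 h after 100 Gy of gamma rays. The line gmi1-1 carries a T-DNA insertion in GMI1 (AT5G24280), a gene known to be induced by gamma rays and mitomycin C through the kinase ATM. The series asks whether GMI1 takes part in regulating the transcriptional response to irradiation. Values are log2 expression as deposited, with array medians between 4.23 and 4.81, and 9889 loci were tested.

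GMI1 rose from near background to a high level in irradiated wild type and was low on all 6 gmi1-1 arrays. The log2 value of its probe set was 2.53, 1.87 and 2.34 in wild type untreated replicates 1, 2 and 3 and 9.97, 10.92 and 10.46 in the irradiated replicates. In gmi1-1 it was 1.66, 1.31 and 1.24 untreated and 1.44, 1.60 and 1.29 irradiated. The means were 2.25 ± 0.34 (SD, n = 3) and 10.45 ± 0.48 in wild type, and 1.40 ± 0.23 and 1.44 ± 0.16 in gmi1-1. GMI1 thus rose by 8.20 in wild type (SE 0.27, adjusted p = 1.5e-08), whereas the gmi1-1 difference was 0.04 (SE 0.27). With untreated wild type near background, the size of its rise is approximate. Where the probes lie relative to the insertion is not known, so a truncated transcript outside them would not be seen.

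**Figure D1:**
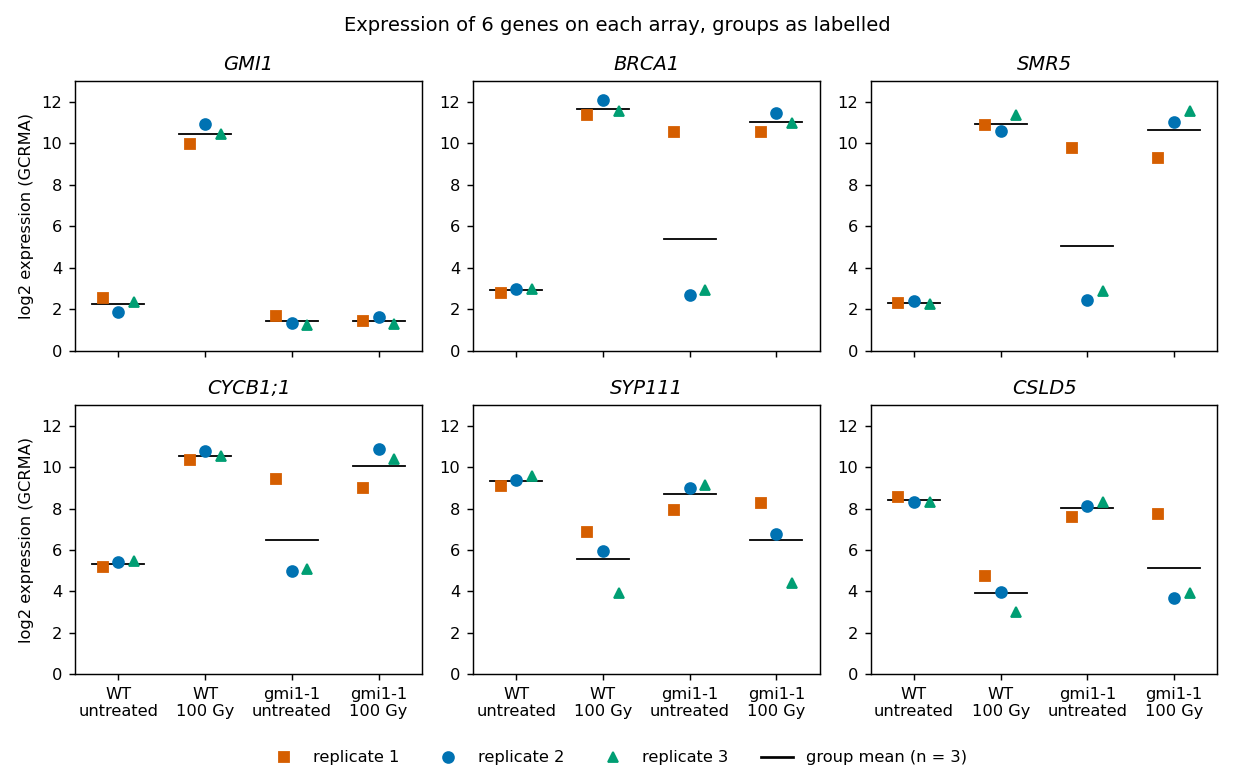
Log2 expression (y axis) of GMI1, BRCA1, SMR5, CYCB1;1, SYP111 and CSLD5 on each of the 12 arrays, by group as labelled (x axis), with replicates by symbol and group means (n = 3) as lines. GMI1 lay between 1.24 and 1.66 on all gmi1-1 arrays, while BRCA1 in gmi1-1 replicate 1 read 10.54 on the array labelled untreated and 10.56 on the array labelled irradiated.

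Damage-induced genes were already high in 1 library labelled gmi1-1 untreated. BRCA1 (AT4G21070), a repair gene, was at 10.54 in the library labelled gmi1-1 untreated replicate 1 and at 2.70 and 2.90 in gmi1-1 untreated replicates 2 and 3, while the library labelled gmi1-1 irradiated replicate 1 had 10.56. These 2 libraries were each other's closest array (Pearson r across loci 0.990), with 120 loci differing by more than 1. That is near the 121 between gmi1-1 untreated replicates 2 and 3, while the untreated and irradiated arrays of gmi1-1 replicate 2 differed at 1563 and those of replicate 3 at 2770. On a scale where 0 and 1 are the untreated and irradiated levels of gmi1-1 replicates 2 and 3, the loci that rose stood at 0.796 in the library labelled untreated and 0.705 in the library labelled irradiated. On the same scale, the loci that fell stood at 0.438 and 0.410. On the scale of wild type replicates 2 and 3, wild type replicate 1 stood at 0.190 untreated and 0.849 irradiated for loci that fell, so a part of this position is shared with replicate 1 of wild type. Both have the low GMI1 values of the mutant. The gmi1-1 irradiated replicate 3 array also stood apart, with an interquartile range of 4.70 against 5.28 to 5.83 on the others and a difference of the 5' and middle GAPDH control probe sets of -1.30 against -0.47 to -0.17.

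**Figure D2:**
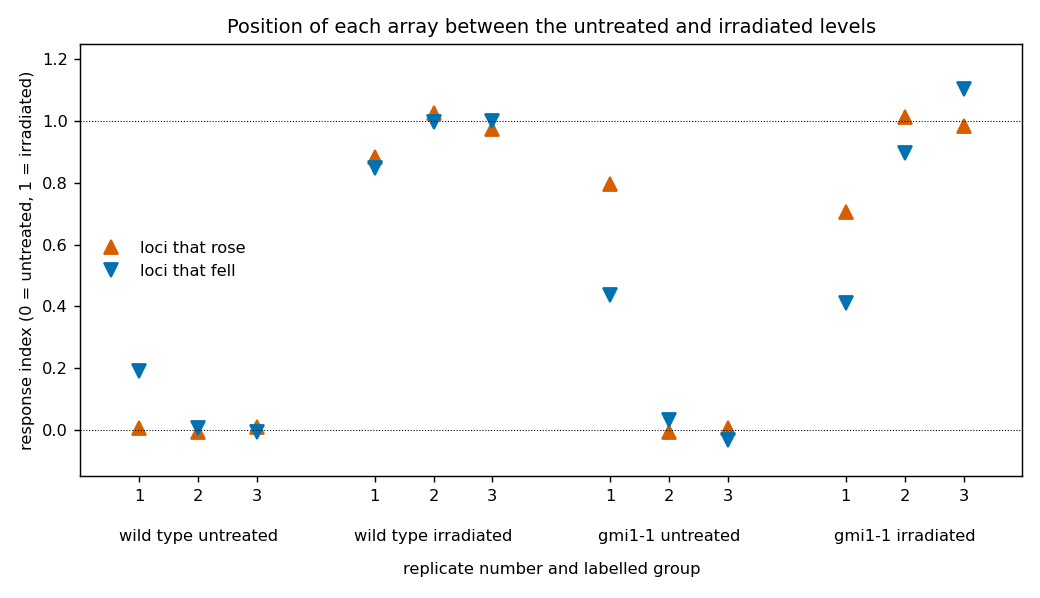
Response index of each array (y axis, no unit), the median position of 65 loci that rose and 69 that fell between the untreated (0) and irradiated (1) levels of replicates 2 and 3 of the same genotype, by labelled group and replicate (x axis). The libraries labelled gmi1-1 untreated and irradiated replicate 1 lay at 0.796 and 0.705 for loci that rose and at 0.438 and 0.410 for loci that fell.

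In wild type, some genes of DNA repair and cell cycle arrest rose by log2 changes of up to 8.76 within 1.5 h of irradiation, and 11 of 16 genes of G2 and M phase fell. BRCA1 went from 2.91 ± 0.11 to 11.67 ± 0.37 (SD, n = 3) (log2 change 8.76, SE 1.53, adjusted p = 0.0092), from a level near background, so the size of its change is approximate. SMR5 (AT1G07500), an inhibitor of cyclin-dependent kinases, rose by 8.64 (SE 1.46, adjusted p = 0.0088). The deepest fall was that of CSLD5 (AT1G02730), a cellulose synthase-like gene, at -4.50 (SE 0.85, adjusted p = 0.012). In all, 449 loci changed, of which 317 rose and 132 fell, and 426 of them by a log2 of 1 or more. With median centring 306 rose and 224 fell, with quantile normalization 311 and 167, and with array weights the balance turned, at 588 and 819. The median over all loci was -0.11 in wild type, -0.23 in gmi1-1 and -0.17 over both genotypes, and every change is best read against it. Counts rest on few arrays: 176 loci were called without wild type untreated replicate 2, 167 without untreated replicate 3, 111 without irradiated replicate 2 and 250 without irradiated replicate 3. Since the spread is pooled over the 4 groups, the count was 726 (409 rose, 317 fell) without the libraries labelled gmi1-1 untreated and irradiated replicate 1, and 857 when gmi1-1 irradiated replicate 3 was left out as well.

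Beside these, the 15 largest rises in wild type included XRI1 (AT5G48720), a gene known from its induction by X-rays, at 8.31, TRFL10 (AT5G03780), a TRF-like gene, at 7.64, PARP2 (AT4G02390), a poly(ADP-ribose) polymerase, at 7.38. Another was SMR4 (AT5G02220), a relative of SMR5, at 6.72. The transcription factors NAC103 (AT5G64060) and WRKY25 (AT2G30250) rose by 6.81 and 6.05, the protein kinase gene SIP4 (AT2G30360) by 7.05 and the small GTPase gene ROP9 (AT4G28950) by 5.97. GEX1 (AT5G55490), known from gametes, rose by 7.06. KCS17 (AT4G34510), a ketoacyl-CoA synthase of fatty acid elongation, rose by 5.95, and AHP2 (AT1G13330), the HOP2 homolog of meiotic recombination, by 5.86. Among the falls were SYP111 (AT1G08560), the syntaxin of the cell plate, at -3.77 (adjusted p = 0.0326), HIK (AT1G18370), a kinesin of cytokinesis, at -2.88. CYCB1;4 (AT2G26760), a mitotic cyclin, was at -3.12. The early nodulin-like genes ENODL13 (AT5G25090) and ENODL14 (AT2G25060) were at -3.96 and -3.03. GSTF11 (AT3G03190), a glutathione transferase, fell by 3.65, SOT17 (AT1G18590), a sulfotransferase of glucosinolate synthesis, by 3.08, and CMR1 (AT3G14190) and ATN (AT3G05330) both by 3.30. Of the 25 genes ranked, 13 lost their call without wild type irradiated replicate 2, among them BRCA1, XRI1, TRFL10, PARP2, ROP9, KCS17, CSLD5, SYP111, CMR1, CYCB1;4, ENODL14 and HIK, with adjusted p up to 0.099 (BRCA1 0.0536). Without wild type irradiated replicate 3, CSLD5, SYP111, ENODL14 and HIK lost theirs (up to 0.106). Without untreated replicate 1 it was SYP111, ENODL14 and HIK (up to 0.0662), and without untreated replicate 2 these and CYCB1;4 (up to 0.118). Without untreated replicate 3 it was SYP111, CMR1, ENODL14 and HIK (up to 0.12), and without gmi1-1 irradiated replicate 2 ENODL14 (0.0506). With each array left out, the change of BRCA1 ran from 8.55 to 8.90 and that of XRI1 from 8.22 to 8.44. That of SYP111 ran more widely, from -4.415 to -2.94. Over all named genes and contrasts, 29 calls were lost without wild type irradiated replicate 2.

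All 14 tested damage response markers rose in wild type (camera adjusted p = 4.4e-23), and 14 when adjusted over the list alone. Among them were PARP1 at 5.66, the cyclin CYCB1;1 at 5.20 (adjusted p = 0.0105), the cell cycle kinase WEE1 at 3.28 (adjusted p = 0.0088) and TSO2, a ribonucleotide reductase subunit, at 2.28 (adjusted p = 0.0251). Of 8 genes of homologous recombination 3 rose, also when adjusted over the list alone (camera adjusted p = 8.4e-04). Among them were BRCA1 and RAD54, the last by 3.42 (adjusted p = 0.0132), while SMC5 was at 0.82 (adjusted p = 0.26). Of 6 genes of end joining 3 rose, again 3 adjusted over the list alone (camera adjusted p = 0.0017): PARP1, PARP2 and the DNA ligase ATLIG4, the last by 2.24 (adjusted p = 0.0092). The KU70 subunit of the end-binding complex was at 0.02. With an estimated correlation these 3 lists had adjusted p = 0.112, 0.112 and 0.144, and without the libraries labelled gmi1-1 untreated and irradiated replicate 1 the damage response markers had adjusted p = 0.0098 with an estimated correlation. On balance the genes of these 3 lists moved upward by limma's fry as well (adjusted p = 0.0025, 0.0092 and 0.0157).

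Of 7 excision and photo repair genes none passed over all loci in limma, and 3 rose when adjusted over the list alone (camera adjusted p = 0.0286, and adjusted p = 0.298 with an estimated correlation). Examples are ERCC1 at 0.83 (adjusted p = 0.132) and UVH3 at 0.65 (adjusted p = 0.156), both of nucleotide excision repair. That list lost its call without wild type untreated replicate 3 (0.0552), and without wild type irradiated replicate 2 (0.0944). It was lost too without the libraries labelled gmi1-1 untreated and irradiated replicate 1 (0.0586), without these and gmi1-1 irradiated replicate 3 (0.0589), with quantile normalization (0.0769) and with no filter (0.0907). Of 7 damage checkpoint kinases and sensors, WEE1 and ATRAD17 (AT5G66130), a checkpoint clamp loader, rose and the histone gene H2AXA fell by 0.98 (adjusted p = 0.0345), 2 and 1 also when adjusted over the list alone. The list did not pass (camera adjusted p = 0.189), and ATM and SOG1, the kinase and the transcription factor at the head of the response, were both at 0.24. Of 6 cohesin and SMC genes 0 passed in limma over all loci and 0 adjusted over the list alone (camera adjusted p = 0.344), with SMC5 at 0.82 and SCC3 at 0.22.

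Of 16 genes of G2 and M phase, 11 fell and 1 rose in wild type, and 14 fell and 1 rose when adjusted over the list alone (camera adjusted p = 2.5e-08, and adjusted p = 0.144 with an estimated correlation). The mitotic kinase AUR1 fell by 2.63, and the cyclins CYCB1;3 and CYCB2;4 fell by 2.31 and 2.07 (adjusted p = 0.0123 and 0.0107). The 1 that rose was CYCB1;1, known as a damage-induced cyclin. Of 18 genes of S phase and replication, 2 rose and 1 fell over all loci, and 2 rose and 6 fell when adjusted over the list alone (camera down, adjusted p = 0.0133, and adjusted p = 0.413 with an estimated correlation). RNR1 and TSO2, both of ribonucleotide reductase, rose by 2.29 and 2.28, and PCNA1, the replication clamp, fell by 1.12 (adjusted p = 0.0394). The list lost its call with a filter at a log2 value of 6 (0.106). Of 10 CDK inhibitors, SMR5 and SMR4 rose and ICK6 fell by 0.86 (adjusted p = 0.0272), against 4 and 2 adjusted over the list alone (camera adjusted p = 0.365). Its median was -0.14 and its mean 1.34.

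Some early stress genes rose in wild type too. Of 9 touch and early stress genes 5 rose, and 7 when adjusted over the list alone (camera adjusted p = 1.1e-07, and adjusted p = 0.112 with an estimated correlation). Among them were the zinc finger gene STZ by 5.56 (adjusted p = 0.0102), WRKY33 by 4.75 (adjusted p = 0.012), ERF6 by 3.06 (adjusted p = 0.0192) and TCH4, a xyloglucan-modifying enzyme, by 2.06 (adjusted p = 0.0088). Of 12 oxidative stress genes 3 rose, and 4 when adjusted over the list alone (camera adjusted p = 9.2e-06, and adjusted p = 0.144 with an estimated correlation): STZ, the kinase AGC2-1 (AT3G25250) by 5.52 and AT2G21640 by 4.01. Of 5 salicylate and defence genes, WRKY70 rose by 1.83 (adjusted p = 0.013) and PAD3, of camalexin synthesis, by 1.45 (adjusted p = 0.0494), 2 also when adjusted over the list alone (camera adjusted p = 0.0050, and adjusted p = 0.112 with an estimated correlation). Since labels do not say whether untreated seedlings were handled like the irradiated ones, handling may be part of this contrast.

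The lists of heat shock, auxin, ethylene, jasmonate, abscisic acid, clock and tissues did not pass camera in wild type. Of 7 heat shock genes 0 passed in limma over all loci or adjusted over the list alone (camera adjusted p = 0.784), with HSFA3 at 0.54 and HSA32 at -0.48. Their mean level did not follow the treatment: it was 6.22 to 6.80 on the 4 replicate 1 arrays, 6.40 in wild type irradiated replicate 2 and 6.85 in gmi1-1 irradiated replicate 2, and 8.11 to 8.66 on the others. Of 9 auxin genes IAA5 rose by 2.99 (adjusted p = 0.0466), and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.943). The list had a median of -0.30 and a mean of 0.09. Of 6 ethylene genes none passed over all loci, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.943), with ACS6 at 0.84 and HLS1 at -1.09. Of 7 clock genes none passed over all loci and 1 rose adjusted over the list alone (camera adjusted p = 0.062), with ELF3 at 0.88 and TOC1 at 0.57. Over all loci or adjusted over the list alone, none passed in limma among 3 jasmonate genes (camera adjusted p = 0.943; MYC2 0.14, LOX2 -0.19), and 4 genes of abscisic acid and drought (0.948; LTI78 0.57, ABI1 -0.40). Nor did any pass among 7 root markers (0.632; SHV2 -0.77, SHR -0.65) and 3 genes of the shoot meristem and stomatal lineage (0.784; TMM -0.47, SPCH -0.11). The jasmonate and abscisic acid lists leaned up in camera with medians of -0.19 and -0.21. The photosynthesis list was not analysed here, and none of 4 measured seed storage genes reached the level needed for a test.

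In gmi1-1 as labelled no locus passed the test, while replicates 2 and 3 on their own showed rises of damage response genes of up to 8.64. With all 12 arrays 0 loci were called in limma, with 1306 at an unadjusted p under 0.05. The smallest adjusted p was 0.158, of LCR67 (AT1G75830), a defensin-like gene, at -2.93 (SE 0.42). SOT17 at -2.18 and TMM, a receptor of stomatal patterning, at -1.40 followed (both adjusted p = 0.234). Among the lists that passed with all 12 arrays, the damage response markers leaned up (camera adjusted p = 3.0e-26, 13 rose adjusted over the list alone). So did touch and early stress (3.0e-13, 6 rose adjusted over the list alone), oxidative stress (2.4e-08, 4) and end joining (4.6e-04, 2), while G2 and M phase leaned down (0.0027, 4 fell and 1 rose). With an estimated correlation they had adjusted p = 0.069, 0.069, 0.086, 0.0935 and 0.446, and limma's fry gave 0.152 for the damage response markers. The count was 327 without the library labelled gmi1-1 untreated replicate 1, 305 without the library labelled gmi1-1 irradiated replicate 1 and 1 without wild type irradiated replicate 1. It was 750 (243 rose, 507 fell) without both doubted libraries numbered 1, and 343 (213 rose, 130 fell) without these and gmi1-1 irradiated replicate 3, so the balance of rises and falls turned with that array. The G2 and M phase list lost its call without gmi1-1 irradiated replicate 2 (0.0583) and with a filter at a log2 value of 6 (0.179).

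Without the libraries labelled gmi1-1 untreated and irradiated replicate 1, which leaves 2 arrays in each gmi1-1 group, the largest rises included those of SMR5 by 8.64 (SE 0.31, adjusted p = 7.2e-08), BRCA1 by 8.44 (SE 0.29, adjusted p = 7.2e-08) and XRI1 by 8.17 (SE 0.25, adjusted p = 7.0e-08). PARP2 rose by 7.68, GEX1 by 6.53, SMR4 by 6.46, ROP9 by 6.23, NAC103 by 6.09 and ATRAD17 by 5.85. Among the falls were CSLD5 by 4.42, GA3OX1 (AT1G15550), of gibberellin synthesis, by 4.36. The xyloglucan-modifying XTH12 (AT5G57530) and XTH13 (AT5G57540) fell by 4.31 and 4.10, and CMR1 by 3.66. ENODL15 (AT4G31840) fell by 4.38, ESE3 (AT5G25190), an ethylene response factor, by 3.86, RHS18 (AT5G22410), of root hairs, by 3.85 and BT2 (AT3G48360) by 3.57. Without gmi1-1 irradiated replicate 3 as well, 6 of these lost their call: ENODL15 (adjusted p = 0.272), XTH12 (0.104), XTH13 (0.0698), ESE3 (0.0855), RHS18 (0.161) and BT2 (0.278).

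By list, the gmi1-1 response without both libraries numbered 1 held 13 of 14 damage response markers that rose, the other being GMI1 at 0.17, and 13 adjusted over the list alone (camera adjusted p = 1.1e-51, and adjusted p = 0.0060 with an estimated correlation). Of 9 touch and early stress genes 6 rose, 7 adjusted over the list alone (5.7e-16, and adjusted p = 0.0128 with an estimated correlation), with WRKY33 at 4.78 and ERF6 at 4.12. Of 12 oxidative stress genes 5 rose, 6 adjusted over the list alone (4.4e-13, and adjusted p = 0.0141 with an estimated correlation), with STZ at 5.81. Of 16 genes of G2 and M phase 11 fell and 1 rose, 12 and 1 adjusted over the list alone (3.9e-04, and adjusted p = 0.399 with an estimated correlation), with SYP111 at -3.49 and AUR1 at -2.40. Of 18 genes of S phase and replication 7 fell and 2 rose, 11 and 2 adjusted over the list alone (0.0318, and adjusted p = 0.475 with an estimated correlation), with the replicative helicase genes MCM4 at -2.51 and MCM3 at -2.06. Of 8 homologous recombination genes 3 rose, 3 adjusted over the list alone (1.3e-05, and adjusted p = 0.0766 with an estimated correlation, median -0.10 and mean 2.30), with RAD54 at 2.76.

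Taken over both genotypes and all 12 arrays, irradiation changed 1026 loci, of which 404 rose and 622 fell, and 591 changed by a log2 of 1 or more. All 14 damage response markers rose, 14 adjusted over the list alone (camera adjusted p = 3.8e-25, and adjusted p = 0.078 with an estimated correlation), GMI1 by its rise in wild type alone. Of 9 touch and early stress genes 7 rose, 8 adjusted over the list alone (8.2e-10, and adjusted p = 0.078 with an estimated correlation). Of 16 genes of G2 and M phase 13 fell and 1 rose, 14 and 1 adjusted over the list alone (6.1e-06, and adjusted p = 0.223 with an estimated correlation). Of 18 genes of S phase and replication 6 fell and 2 rose, 13 and 2 adjusted over the list alone (0.0372, and adjusted p = 0.453 with an estimated correlation). This list lost its call with the replicate block (0.0673), a filter at a log2 value of 6 (0.161) and an intensity trend (0.052). It did so too without the library labelled gmi1-1 untreated replicate 1 (0.0674), wild type irradiated replicate 2 (0.0612) or gmi1-1 irradiated replicate 2 (0.0841). The share of rises depends on the scaling, being 39.4% as deposited, 52.6% after quantile normalization and 56.3% after median centring. The count was 513 and 526 without wild type untreated replicates 2 and 3, 503 and 474 without gmi1-1 untreated replicates 2 and 3, and 627 without wild type irradiated replicate 2. It was 1889 (542 rose, 1347 fell) without the libraries labelled gmi1-1 untreated and irradiated replicate 1.

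Across the 1026 loci, the slope of the gmi1-1 change on the wild type change was 0.649 (jackknife SE 0.398) with all 12 arrays, and the Pearson correlation across all 9889 loci, which are not independent replicates, was 0.888. The slope was 0.944 over the 1528 loci called without the library labelled gmi1-1 untreated replicate 1. It was 1.09 over the 1889 loci called without both gmi1-1 libraries numbered 1, so the loci changed along with the arrays. In that last fit, wild type and gmi1-1 shared 235 of 409 and 243 loci that rose, where independence would give 10.1. They shared 247 of 317 and 507 that fell, where it would give 16.3. The 2 comparisons share no array, but they share 1 estimate of the spread per locus. Same-numbered arrays also deviate together (r above 0.1 in 12 of 18 pairs). The calls are thus not independent, and these baselines are only a rough guide.

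**Figure D3:**
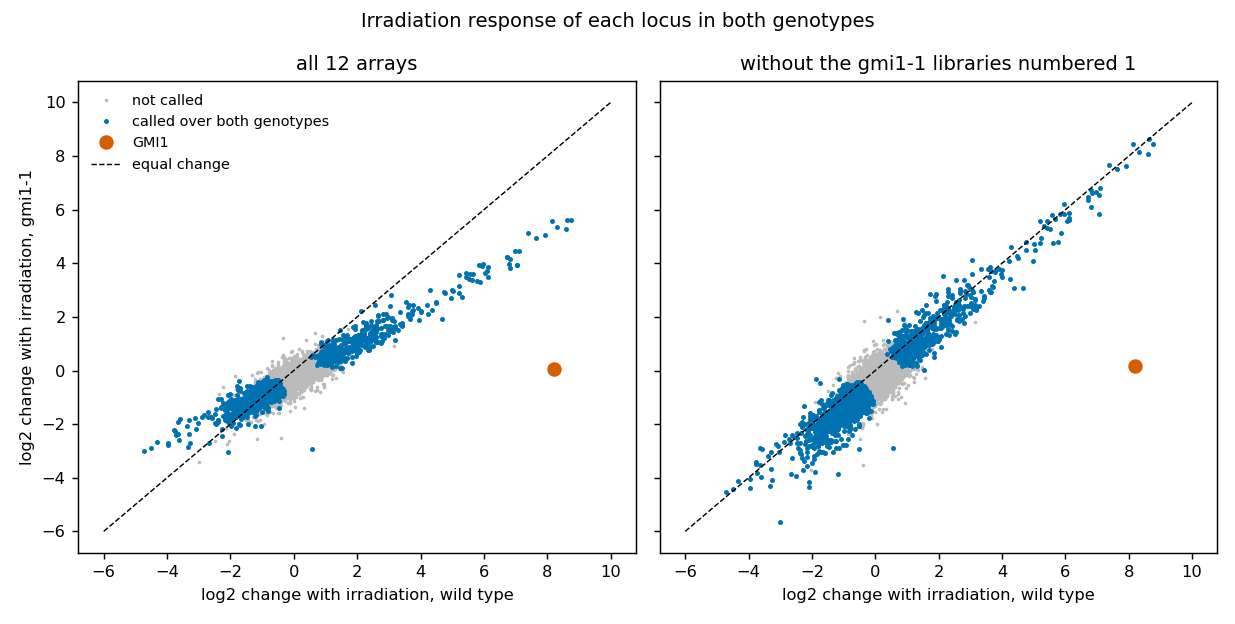
Log2 change with irradiation in gmi1-1 (y axis) against wild type (x axis) for each of 9889 loci, with all 12 arrays (left) and without the gmi1-1 libraries numbered 1 (right), loci called over both genotypes in blue, GMI1 in orange, the dashed line marking equal change. The slope over called loci is 0.649 on the left and 1.09 on the right, and GMI1 lies at 8.20 on the x axis in both.

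The question of the series is the difference in the irradiation effect between genotypes, and GMI1 itself was the 1 locus that passed. Its gmi1-1 effect was lower by a log2 of 8.16 than that of wild type (difference -8.16, SE 0.38, adjusted p = 8.5e-07), between -8.40 and -7.93 with any 1 array left out, and -8.03 without both gmi1-1 libraries numbered 1 (adjusted p = 2.9e-05). With untreated wild type and both gmi1-1 groups near background, the size of this difference is approximate. At an unadjusted p under 0.05 there were 184 loci. LCR67 at -3.49 (SE 0.59, adjusted p = 0.384) and PME12 (AT2G26440), a pectin methylesterase, at -1.26 (adjusted p = 1) came next without passing. The damage response markers leaned to a smaller response in gmi1-1 with all 12 arrays (median -2.16, camera adjusted p = 1.7e-10, and adjusted p = 0.582 with an estimated correlation). GMI1 was the 1 of 14 called over all loci and adjusted over the list alone, and limma's fry gave adjusted p = 0.428. With each array left out in turn the list kept its call (1.1e-20 to 0.0083), but without GMI1 among its members it had 0.446 when the library labelled gmi1-1 untreated replicate 1 was left out. Without the libraries labelled gmi1-1 untreated and irradiated replicate 1 this list had adjusted p = 0.932 and the opposite direction. Over the 13 members other than GMI1, the difference of array means was -2.17 (95% interval -6.25 to 1.92) with all 12 arrays, -0.45 (-1.65 to 0.75) without the library labelled gmi1-1 untreated replicate 1 alone, and -0.04 (-0.57 to 0.50) without both libraries. The last fit leaves out an irradiated array whose response was partial, so it cannot rule out a weaker response in gmi1-1. The G2 and M phase list leaned to a smaller fall in gmi1-1 (median 0.90, camera adjusted p = 8.6e-12, and adjusted p = 0.451 with an estimated correlation), with 0 of 16 called in limma over all loci or adjusted over the list alone. It had a median of 0.23 without both libraries numbered 1 (1.0e-05, and adjusted p = 0.476 with an estimated correlation). The median over all loci was -0.26 in that fit.

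Without irradiation, gmi1-1 and wild type differed at 1 locus with all 12 arrays: LCR67 was higher in gmi1-1, at 5.46 ± 0.36 against 1.86 ± 0.23 (SD, n = 3; log2 difference 3.60, SE 0.42, adjusted p = 0.0205), and higher in 3 of 3 gmi1-1 arrays (5.36, 5.15 and 5.86). Its wild type level lies near background, so the size of this difference is approximate. At an unadjusted p under 0.05 there were 42 loci, and NET4B (AT2G30500) at -0.92 and GMI1 at -0.84 followed (both adjusted p = 1). The count was 0 in limma without any 1 of wild type untreated replicates 1, 2 and 3, gmi1-1 untreated replicates 2 and 3, the library labelled gmi1-1 irradiated replicate 1, and gmi1-1 irradiated replicates 2 and 3. The LCR67 difference itself stayed between 3.395 and 3.75 with each array left out. Without the library labelled gmi1-1 untreated replicate 1 the count was 2: LCR67 (3.65, adjusted p = 0.0429) and the expansin EXPA8 (AT2G40610; 2.10, adjusted p = 0.0147). Without both libraries numbered 1 only EXPA8 passed (2.10, adjusted p = 0.0286), LCR67 having an adjusted p = 0.0961. With all 12 arrays the EXPA8 difference was 1.01 (adjusted p = 1), and it ran from 0.33 to 2.10 with each array left out. The damage response markers leaned up in untreated gmi1-1 (median 1.39, camera adjusted p = 5.6e-12, and adjusted p = 0.374 with an estimated correlation), with 0 of 14 called in limma over all loci or adjusted over the list alone. That direction turned without the library labelled gmi1-1 untreated replicate 1 (0.127), and array weights ended the call (0.337). The oxidative stress list leaned up by a narrow margin (0.0334, and adjusted p = 0.598 with an estimated correlation) and turned without the same library (0.376). It lost its call with the replicate block (0.135), no filter (0.187), median centring (0.0536) and array weights (0.855). The same held without wild type untreated replicate 1 (0.0813) or 2 (0.124), wild type irradiated replicate 2 (0.0552) or gmi1-1 irradiated replicate 2 (0.0531). Touch and early stress genes leaned up as well (median 0.78, camera adjusted p = 3.5e-11, and adjusted p = 0.0834 with an estimated correlation), with 1.0e-18 to 0.0276 when each array was left out. The median was 0.42 without the library labelled gmi1-1 untreated replicate 1 (0.0276). The arrays were uneven: the list's mean level was 6.31 in that library and 4.54 and 5.05 in gmi1-1 untreated replicates 2 and 3. In wild type untreated replicates 1, 2 and 3 it was 4.23, 4.63 and 4.64, so gmi1-1 replicate 2 lay below wild type replicates 2 and 3. The G2 and M phase genes leaned down (median -0.52, 8.4e-04, and adjusted p = 0.524 with an estimated correlation), with 6.3e-06 to 0.0353 when each array was left out, although a filter at a log2 value of 6 gave 0.217 and array weights 0.0619. The CDK inhibitors leaned up (0.0020, and adjusted p = 0.0834 with an estimated correlation) and lost their call without wild type untreated replicate 1 (0.0993) or the library labelled gmi1-1 untreated replicate 1 (0.064), and with array weights (0.111). In these 4 lists limma called 0 loci over all loci or adjusted over the list alone.

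Among irradiated seedlings, GMI1 was lower in gmi1-1 than in wild type by a log2 difference of -9.01 (SE 0.27, adjusted p = 5.1e-09), lower in 3 of 3 arrays, a size that is approximate with the gmi1-1 level near background. No other locus passed, with 764 at an unadjusted p under 0.05. NET4B at -1.43 and ATJ6 (AT5G06910), a J-domain chaperone gene, at -0.91 followed (both adjusted p = 0.628). Touch and early stress genes leaned up in irradiated gmi1-1 (median 0.15, camera adjusted p = 0.0010, and adjusted p = 0.773 with an estimated correlation) with 0 of 9 called in limma over all loci or adjusted over the list alone. This list lost its call without gmi1-1 irradiated replicate 3 (0.872) and without wild type irradiated replicate 3 (0.0713), and with median centring (0.326), no filter (0.138) and array weights (0.115). The G2 and M phase genes leaned up too (median 0.23, 6.2e-07, and adjusted p = 0.773 with an estimated correlation, 0 of 16 called in limma). They lost their call without the library labelled gmi1-1 irradiated replicate 1 (0.178) and without wild type irradiated replicate 3 (0.0713), and with no filter (0.112). Over both treatments GMI1 was the 1 locus called (-4.93, SE 0.19, adjusted p = 9.9e-08), with 559 at an unadjusted p under 0.05. The size of this GMI1 difference is approximate as well, with untreated wild type and both gmi1-1 groups near background. LCR67 at 1.85 and NET4B at -1.18 did not pass (both adjusted p = 0.202). Touch and early stress genes leaned up over both treatments (median 0.515, camera adjusted p = 1.8e-10, and adjusted p = 0.184 with an estimated correlation), with 0 of 9 called in limma and 1.4e-16 to 0.0012 when each array was left out. The arrays were uneven here too: the list's mean level in gmi1-1 replicate 2 was 4.54 untreated and 7.17 irradiated. In wild type replicate 2 it was 4.63 and 7.20. The damage response markers leaned up too (median 0.36, 0.0060, and adjusted p = 0.754 with an estimated correlation), with GMI1 the 1 of 14 called. They lost their call without gmi1-1 irradiated replicate 3 (0.209), with no filter (0.452) and with both scalings (quantile normalization 0.737, median centring 0.945). Their direction turned without the library labelled gmi1-1 untreated replicate 1 (6.1e-04) and with array weights (0.735). Without GMI1 among its members the list had camera adjusted p = 0.0686 without that library, and adjusted p = 0.685 with an estimated correlation. The CDK inhibitors also leaned up (0.0353, and adjusted p = 0.197 with an estimated correlation). Their call was lost without wild type untreated replicate 1 (0.203), the library labelled gmi1-1 untreated replicate 1 (0.116), wild type irradiated replicate 2 (0.235) or gmi1-1 irradiated replicate 3 (0.379). It was also lost with quantile normalization (0.401), median centring (0.422), no filter (0.629), a filter at a log2 value of 6 (0.119) and array weights (0.453). The count of loci over both treatments was 2 without the library labelled gmi1-1 untreated replicate 1, 2 without both libraries numbered 1, where EXPA8 joined GMI1, and 3 without wild type irradiated replicate 1.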

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

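The tests of the doubted gmi1-1 libraries and of the damage response markers were chosen only after the result was seen, while those of the splits, the genes next to GMI1, gene length and between-array scaling were chosen before.

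Between genotypes, 3 results were flagged by the test of the difference itself, the 2 lists among them only at camera's preset correlation. The GMI1 effect was lower in gmi1-1 by a log2 difference of -8.16. The damage response markers leaned to a smaller response in gmi1-1 (camera adjusted p = 1.7e-10, and adjusted p = 0.582 with an estimated correlation), and the G2 and M phase genes to a smaller fall (8.6e-12, and adjusted p = 0.451 with an estimated correlation). Neither list held a called locus other than GMI1 in limma, with 184 loci at an unadjusted p under 0.05. The 10 nearest neighbours of GMI1 among the loci kept by the filter, 5 on each side, were not called between irradiated gmi1-1 and wild type in limma. The smallest adjusted p was 0.628 for 3 of them, among them SOS3.

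The libraries labelled gmi1-1 untreated replicate 1 and gmi1-1 irradiated replicate 1 both hold a partial irradiation response. An exchange of their labels is argued against, since neither lay at the untreated level of loci that rose (index 0.705 at least). A fully irradiated library under a wrong label cannot be ruled out. Neither reached the full fall (0.438 at most), where wild type irradiated replicate 1 stood at 0.849 on the wild type scale. Both scales rest on replicates 2 and 3. The closest array of wild type irradiated replicate 1 was the library labelled gmi1-1 untreated replicate 1 (Pearson r across loci 0.984), with 283 loci differing by more than 1. A response in all untreated gmi1-1 seedlings is argued against by the 13 damage response markers other than GMI1. Their mean level was 4.58 and 4.74 in gmi1-1 untreated replicates 2 and 3, against 4.74 to 4.81 in untreated wild type. The index of these replicates, 4.0e-04 at most on the wild type scale, cannot decide, since its loci were picked by their rise from these same arrays. A response weaker by a common factor is argued against by the lag behind the other irradiated libraries. The Spearman correlation across loci of this lag with the size of the rise was 0.0168 and 0.0436. A mixture of untreated and irradiated RNA in both libraries cannot be told apart from other causes: the share of the irradiated level reached and the share of the untreated level left sum to 0.808 and 0.902, but 9 of the 10 other arrays also lay within the bound set for a mixture, from 0.687 to 1.24 over all 10. A lower dose or an earlier harvest of both was not tested and stays open, and the labels were kept.

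For the smaller response of the damage response markers in gmi1-1, it is not settled whether the GMI1 probe set alone accounts for it. The list without GMI1 still passed with all 12 arrays at the preset correlation (camera adjusted p = 2.2e-05). It did not pass with an estimated correlation (adjusted p = 0.621) or by limma's fry (adjusted p = 0.503), and 0 of 13 members were called. The libraries numbered 1 could account for the lean of these other 13 members: without both, their median difference went from -2.07 to 0.0033. Without both, the camera test of these members against all loci even leaned the other way (adjusted p = 0.0253, and adjusted p = 0.812 with an estimated correlation). Their median of 0.0033 stood beside a median of -0.26 over all loci in that fit, and limma's fry gave adjusted p = 0.995. This lean therefore does not show a stronger response of these members in gmi1-1. A loss of GMI1 that weakens the response cannot be told apart from a defect of these libraries: without the library labelled gmi1-1 untreated replicate 1 alone, the mean difference was -0.45 (95% interval -1.65 to 0.75). Without both it was -0.04 (-0.57 to 0.50), but that fit leaves out an irradiated library because its response was partial.

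The gmi1-1 irradiated replicate 3 array stands apart from the others, with 1629 loci more than 1 from the mean of the other arrays of its group. Gene length cannot decide on a loss of 5' ends. The Spearman correlation across loci between this array's deviation and gene length was -0.0629, within the -0.324 to 0.485 of the other arrays. That range is wide, and 1 of the 2 arrays it was set against is a doubted library. Its GAPDH difference of -1.30 remains, against -0.47 to -0.17 on the other arrays. Between-array scaling cannot be told apart from other causes: after quantile normalization 1212 loci remained, beside 1205 for the library labelled gmi1-1 irradiated replicate 1, a gap judged too small with the values known. No biological explanation was tested for it.

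Other splits of the arrays were counted for each comparison. For irradiation over both genotypes chance is argued against: the real split gave 1026 loci and the highest of the others 664, with 1 of 100 splits as large. That is the smallest share these splits can give, and same-numbered arrays deviate together, so chance is not excluded. For the count of the difference between genotypes the splits cannot decide: 14 of 100 gave as many loci (1, highest other 1). The same holds for gmi1-1 against wild type over both treatments, with 12 of 100 (1, highest other 2). A split that keeps the irradiated arrays as labelled keeps most of the GMI1 difference, since GMI1 is near background on all untreated arrays. Such shares can thus arise from GMI1 itself, and no conclusion is drawn from them. The 10 splits of 6 arrays are too few for a share under 0.05 in the other comparisons. For irradiation in wild type the real split gave 449 loci and the highest other 0, with 1 of 10 as large. For irradiation in gmi1-1 these were 0 and 3 (10 of 10), for gmi1-1 against wild type untreated 1 and 1 (2 of 10) and irradiated 1 and 0 (1 of 10).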

How the results depend on the processing

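The tests without the doubted gmi1-1 libraries, without GMI1 in the slope and without GMI1 in the damage response list were chosen only after the result was seen. Over all alternatives, 168 values of counts, levels and slopes stayed within their limits and 38 moved; of the list calls 713 kept their side, 109 were lost and 12 reversed; of the named genes 2910 kept theirs, 217 passed anew, 109 were lost and 4 reversed. The limit was a factor of 1.5 for a count, with any call counting as moved where there had been 0, the jackknife SE for the slope, and the direction and side of the threshold for the GMI1 level. All 38 list calls with all 12 arrays were lost with an estimated correlation.

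For irradiation in wild type (449 loci) the count was 297 with a filter at 6, 1407 with array weights (588 rose, 819 fell), 726 without the 2 gmi1-1 libraries numbered 1, 857 without the 3 doubted libraries, and 111 to 591 with each array left out. For irradiation in gmi1-1 (0 loci, limma, 1306 at an unadjusted p under 0.05) it was 417 with array weights, 750 and 343 without the 2 and the 3 libraries, and 0 to 327 with each array left out. Over both genotypes (1026) it was 2594 with array weights, 1889 without the 2 libraries, 591 at a log2 change of 1 or more, and 474 to 1528 with each array left out. For gmi1-1 against wild type untreated (1) it was 0 with a filter at 6, with median centring and without the 3 libraries (limma, 351 at an unadjusted p under 0.05 without the 3), and 0 to 2 with each array left out. Over both treatments (1) it was 2 without the 2 libraries and 1 to 3 with each array left out. The difference between genotypes and gmi1-1 against wild type irradiated gave 1 throughout. The slope, over the loci called in each fit, was 1.09 without the 2 libraries and 0.516 to 0.944 with each array left out. The irradiated GMI1 difference was -9.25 to -8.77 with each array left out. With fewer loci tested a filter changes the count by construction, and the lower spread of the wild type comparison without the 2 libraries follows from pooling; for the rest the cause was not tested.

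Directions that reversed, for which the cause was not tested, were these. The damage response list had adjusted p = 0.932 and 0.868 for the difference between genotypes without the 2 and the 3 libraries. In untreated gmi1-1 against wild type it had 0.105 and 0.208 in those fits, and 2.4e-27 to 0.127 with each array left out. Over both treatments it had 0.735 with array weights, 0.398 and 0.387 without the 2 and the 3 libraries, and 4.0e-09 to 0.209 with each array left out, reversing at 6.1e-04 without the library labelled gmi1-1 untreated replicate 1. The oxidative stress list in untreated gmi1-1 had 0.645 and 0.701 in the same fits and 3.5e-05 to 0.376 with each array left out. Of genes that did not pass in wild type, SCC3 ranged from -0.01 to 0.55, LOX2 from -0.34 to 0.08 (0.02 without wild type irradiated replicate 3) and SPCH from -0.51 to 0.19.

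With the replicate number as a block the counts were 585 in wild type and 1485 over both genotypes and the slope 0.667. Deviations from the group mean correlated above 0.1 in 12 of 18 same-numbered pairs (lowest -0.024), and 11 of 12 arrays did so best with their own number. The share of rises in wild type went from 70.6% to 57.7% with median centring. A robust prior changed no count and has no form for camera. The alternative without cross-hybridising probe sets was void, since none is named so, and a slope over genes called in gmi1-1 was not run with 0 calls. Values near background limit what low loci can show.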

Other observations

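The families of genes sharing a symbol were tested only after the result was seen, as were their scaling alternatives. The WRKY, ERF and NAC families of transcription factors leaned up in irradiated wild type by camera, while most of their members did not pass. Of 19 WRKY genes 7 rose (camera adjusted p = 5.5e-06 over 72 families, and adjusted p = 0.821 with an estimated correlation), among them WRKY46 by 3.09 and WRKY48 by 2.54. Of 9 ERF genes 4 rose (9.3e-04, and adjusted p = 0.821 with an estimated correlation), with ERF105 at 2.81 and ERF104 at 2.56. Of 16 NAC genes 5 rose (0.0402, and adjusted p = 0.821 with an estimated correlation), with NAC046 at 2.88 and NAC053 at 2.61, although the family's median was 0.015. Without the libraries labelled gmi1-1 untreated and irradiated replicate 1, the gmi1-1 response held 5 WRKY genes that rose and 1 that fell (2.1e-07), 4 ERF genes that rose (1.7e-07) and 4 NAC genes that rose and 1 that fell (0.0080), with adjusted p = 0.966, 0.217 and 0.966 with an estimated correlation. These 3 families kept their direction in wild type under quantile normalization and median centring, with 2 ERF genes that rose under each.

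The histone HTA and the SAUR families leaned down in irradiated wild type. Of 8 HTA genes, which encode histone H2A, 2 fell (camera adjusted p = 0.0012, and adjusted p = 0.821 with an estimated correlation), HTA7 by 1.23 and HTA13 by 0.97. Of 25 SAUR genes, known as auxin-responsive genes of cell expansion, 1 fell (0.0014, and adjusted p = 0.821 with an estimated correlation), SAUR50 by 2.13, with a family median of -1.11. Without the libraries labelled gmi1-1 untreated and irradiated replicate 1, 8 of the 25 fell in gmi1-1 (0.0287, and adjusted p = 0.966 with an estimated correlation). That fit keeps gmi1-1 irradiated replicate 3, the array that stands apart, and the family was not tested without it. Of 13 ABCB transporter genes 2 rose in wild type (0.0014, and adjusted p = 0.821 with an estimated correlation), ABCB13 by 3.40 and ABCB1 by 1.75. The HTA, SAUR and ABCB families kept their direction under both scalings.

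The first principal component held 49.2% of the variance, the second 17.0% and the third 13.7%. On the second, the 4 replicate 1 arrays lay between 18.2 and 39.2 and the other 8 below 0. Array weights estimated from the data ran from 0.201 for gmi1-1 irradiated replicate 3 to 4.65 for wild type untreated replicate 2.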
